A study of Mus musculus with 15 samples.

How the data were processed

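Kidneys of C57BL/6 mice with floxed Esrrg alleles, with or without the Sim1-Cre transgene, were the source of polyadenylated RNA, and stranded libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. Groups were taken from the titles: 15 libraries in 6 groups of genotype, sex and age, numbered without repeats, so that no numbers pair libraries across groups. The labels name separate samples of littermates. The deposited p-values measure the spread between the libraries that entered each comparison, and which of the labelled libraries these were is not known. The p-values of the set test described below are computed across genes with a preset correlation and do not measure that spread.

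The submitters' processing notes name the genome build mm10, the aligner STAR, the HOMER suite and DESeq2, and their versions are not given in the sources used here. The deposited files are 3 tables of the authors' own comparisons, with the columns of DESeq2 per the file headers, and hold no value per library. Each gives, per the file headers, a mean of normalized counts over the libraries (a signal that is never negative), a log2 fold change with its standard error, a p-value and an adjusted p-value, and a status. On the values, 100% of the deposited p-values equalled the 2-sided normal p of the log2 fold change over its standard error within 1%, and the authors' adjusted p-values differed by less than 9e-07 from a Benjamini-Hochberg adjustment over the genes with the status OK. The status Low went with means up to 9.995, 9.997 and 9.968 in 3-week males, females and 3-month males, and OK with means from 10.02, 10.0 and 10.01. The status Outlier held 615, 845 and 1516 genes, which have a fold change and no p-value, and its rule is not given in the sources used here. The largest standard errors were 0.44, 0.42 and 1.10, and standard errors with such a ceiling arise where fold changes are moderated towards 0. Whether and how far this was done in each table is not given in the sources used here, so sizes of fold changes across tables carry this limit. The tables were normalized separately, so means of genes were set side by side across them only for their order of magnitude, and totals only as a measure of depth.

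A mean over a few libraries moves in steps of what 1 read is worth in each library. Recurring values under 2 shared by at least 20 genes and not made of smaller ones (tolerance 2.5e-06) gave 4, 4 and 5 libraries, where the labels give 5, 4 and 6. Of the means under 2, 99.4%, 99.9% and 99.9% were whole multiples of these steps, against 0.15%, 0% and 1.25% of random values. The size factors they imply had geometric means of 1.00, 1.00 and 1.00. A further library in the table of 3-week males would need a step of 0.0835, and the lowest mean there is 0.208; in that of 3-month males it would need 0.0681, and the lowest mean is 0.145. In the table of 3-month males 2 steps went with positive and 3 with negative fold changes, and in both others 2 with each. With the ratio read as knockout over control, the steps give 2 knockout libraries in each table, where the labels give 3, 2 and 3. For 3-week males this holds with either direction of the ratio. Which of the labelled libraries entered each table cannot be told from this. The direction of the ratio is not named in the headers and was read as knockout over control, as the report says.

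The design fixed before the data were examined foresaw count models on values per library and, for tables of the authors' comparisons, only their fold changes and p-values. The second case applied. A gene counted as called when the authors' deposited adjusted p was under 0.05, and 27 symbols turned into dates by a spreadsheet were left out, which leaves 23393, of which 21751 were in GENCODE M21 and 23276 in it or among RefSeq names and synonyms. Coordinates are those of GENCODE M21 on GRCm38, the same build as mm10. The interactions and the contrasts between controls were not tested in the planned way, and library quality measures were not computed. Of the 24 gene lists, 23 were offered to the set test and those with at least 5 tested members entered it, with sex chromosome markers kept as a check of labels. The set test was cameraPR of limma on the fold change over its standard error, 2-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a table. It replaces camera on a fitted model, and neither the estimated correlation nor fry could be run without values per library.

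The rule for named genes, also fixed before, took Esrrg, the 8 called genes with the largest positive and the 8 with the largest negative fold change at a mean of at least 5 CPM of the table's total, leaving out predicted gene models, the 6 in each direction called in all 3 tables with the largest mean fold change, and up to 4 members of a list with the smallest p. Some genes that this rule took are not reported here. Genes with opposite calls at the 2 ages were chosen after the data were seen. The uroplakins, Krt1, Krt10 and Lor were chosen once the keratin values, and before their own, had been seen.

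The difference of 2 deposited fold changes was set against the root of the summed squares of their standard errors (2-sided normal p, Benjamini-Hochberg over the genes tested in both tables).

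The alternatives were all chosen after seeing the data. For genes they were an adjusted p under 0.01, genes with the status Outlier or Low kept, a mean of at least 100, an absolute log2 fold change of at least 1, and scaling to the total count of each genotype, computed from means, fold changes and the numbers of libraries read from the steps. For lists they were Outlier genes kept, ranks, fold changes in place of statistics, inter-gene correlations of 0.05 and 0.1, total-count scaling, and subtraction of the running median of 501 genes of like abundance.

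The step search, the adjustment and the set test were tested on simulated data first. The search recovered 5 of 5 simulated libraries for each table. The simulated set tests held 14657 genes for 3-week males, 14146 for females and 12828 for 3-month males. In that order the set test called 6, 5 and 6 of 6 shifted lists. It made 0, 1 and 0 calls among 16, 16 and 15 lists that were not shifted. The correlation between genes in the deposited tables was not estimated, so these simulated calls do not give the error rate of the set test there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.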

Results

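The kidneys compared came from C57BL/6 mice that lacked the nuclear receptor ERRγ, encoded by Esrrg, in the cells reached by the Sim1-Cre transgene, and from Cre-negative littermates with the same floxed alleles. ERRγ is an orphan receptor known to act on genes of mitochondrial energy metabolism, and the series title ties it to mitochondria and to reabsorption in the kidney. The comparisons ask which kidney genes differ between the genotypes. Polyadenylated RNA of 15 kidneys was sequenced in 6 groups. At 3 weeks of age there were 2 control and 3 knockout males and 2 control and 2 knockout females, and at 3 months there were 3 control and 3 knockout males. The values analysed were 3 comparisons of the genotypes, at 3 weeks in males, at 3 weeks in females and at 3 months in males, each with 23420 genes. The fractional steps of the lowest mean counts fitted 4 libraries in the table of 3-week males, 4 in that of females and 5 in that of 3-month males, against 5, 4 and 6 in the labels. By the signs at these steps, and with the ratio read as described below, each comparison rests on 2 knockout kidneys. The mean total of normalized counts, in units of 1e6, was 47.6 in 3-week males, 33.9 in females and 18.8 in 3-month males. Approximate library totals read from those steps lay between 39.5 and 57.1, between 21.4 and 46.3 and between 15.2 and 26.0 in the same units and order. Values per library were not used here, so the errors given are the standard errors of the authors' deposited tables.

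Esrrg itself, on chromosome 1 from 187608791 to 188214885 on the plus strand in GRCm38 (mm10), had a positive fold change in the young kidneys. The authors' deposited table gave it a log2 fold change of 0.82 ± 0.20 (SE, adjusted p = 0.000613) in 3-week males and 1.04 ± 0.17 (adjusted p = 1.70e-08) in 3-week females. At 3 months the authors' deposited table gave -0.87 ± 0.57 and no p-value. A gene's mean count can hold reads of exons outside the deleted part, and the floxed exon is not given in the sources used here, so these values check neither the deletion nor the labels. The tables do not name the genotype on top of the ratio. On their face the positive values of Esrrg at 3 weeks go against knockout on top, and the negative one at 3 months, without a p-value, goes with it. A positive value is read throughout as higher in the libraries labelled knockout, because the series title ties ERRγ to mitochondrial and reabsorptive genes and the lists of mitochondrial, proximal tubule transport and distal convoluted and connecting tubule genes have negative medians in all 3 tables. The principal cell list has positive medians in both tables of males, and the intercalated cell list has one at 3 months. The fall of the mitochondrial, proximal and distal lists is therefore part of the reading and no independent evidence of it. The opposite movement of the injury, immune and matrix genes against them does not depend on it. With the ratio turned, higher and lower would change places in every value, count and share given here.

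In 3-week-old males, the knockout kidneys had less RNA of tubular transport genes and of kallikrein and more of tubular injury genes. Among the genes that fell most, the authors' deposited table gave log2 fold changes of -6.61 ± 0.25 for Gpx6, a glutathione peroxidase, -5.34 ± 0.24 for Tmem207, -4.87 ± 0.23 for Atp4a, the catalytic subunit of the gastric-type proton pump, and -4.48 ± 0.18 for Klk1, tissue kallikrein (SE; adjusted p from 1.34e-99 to 2.95e-152). Pvalb, the calcium-binding parvalbumin of the distal convoluted tubule, Aqp6, a channel of intercalated cells, and Kcnt1, a sodium-activated potassium channel, were at -3.87, -3.85 and -3.85 in the authors' deposited table, followed by Tnn. Among the genes that rose most, the authors' deposited table gave 5.40 ± 0.26 for Pappa2, a protease of insulin-like growth factor binding proteins, 4.27 ± 0.22 for S100a14, 4.25 ± 0.31 for Cyp2j13 and 4.08 ± 0.33 for Krt20, a keratin of injured tubules and of surface cells of urothelium (adjusted p from 1.85e-32 to 1.74e-93). Aldh1l2, a mitochondrial folate enzyme, Thy1, Cyp24a1, the enzyme that inactivates vitamin D, and Egr1, an immediate early transcription factor, rose by 2.87, 2.85, 2.69 and 2.66 in the authors' deposited table. Klk1 and Cyp2j13 belong to families of near-identical genes, so part of their reads may be shared with relatives. By adjusted p under 0.05, 2540 of 14657 tested genes were called, 1291 higher and 1249 lower in the knockout.

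Genes of mitochondrial energy production fell together in 3-week males. Of 43 tested genes of complex I, 31 fell and none rose (36 adjusted over the list alone), with a median log2 fold change of -0.62. Ndufs1 was at -0.82 ± 0.15 and Ndufa9 at -0.74 ± 0.15 in the authors' deposited table. In the list of complexes II to IV and cytochrome c, 23 of 32 fell (26 adjusted over the list alone), among them Sdha at -0.69 ± 0.15 and Uqcrc1 at -0.85 ± 0.19 in the authors' deposited table. Of the ATP synthase and nucleotide exchange genes, 17 of 23 fell (20 adjusted over the list alone), and of the TCA cycle genes 15 of 20 (18 adjusted over the list alone). Idh2 was at -1.12 ± 0.16 and Pcx, pyruvate carboxylase, at -1.05 ± 0.20 in the authors' deposited table. Fatty acid oxidation genes fell in 23 of 34 cases (28 adjusted over the list alone), including Acsm2 at -1.10 ± 0.18 in the authors' deposited table. The mitochondrial ribosome had a median of -0.35, with 15 of 73 genes lower (21 adjusted over the list alone). The set test (limma cameraPR) gave adjusted p = 5.97e-14 for complex I, 8.42e-12 for complexes II to IV, 3.32e-09 for ATP synthase, 5.60e-11 for the TCA cycle, 1.77e-13 for fatty acid oxidation and 6.84e-09 for the mitochondrial ribosome.

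Genes of most nephron segments also fell in 3-week males, and those of collecting duct principal cells went the other way. Proximal tubule transport genes fell in 28 of 45 cases (32 adjusted over the list alone, adjusted p = 7.98e-24 in the set test, and 4.50e-07 with an inter-gene correlation of 0.1). Slc5a2, the main glucose transporter of the early proximal tubule, was at -3.15 ± 0.17 and Slc34a3, a sodium-phosphate cotransporter, at -3.00 ± 0.18 in the authors' deposited table. Thick ascending limb genes had a median of -0.99, with 12 of 20 lower and 2 higher (12 and 2 adjusted over the list alone, adjusted p = 3.63e-22). Egf was at -2.87 ± 0.19 in the authors' deposited table. Of the distal convoluted and connecting tubule genes, 12 of 23 fell and 1 rose (16 and 2 adjusted over the list alone, adjusted p = 6.97e-19). Slc12a3, the thiazide-sensitive cotransporter, was at -2.30 ± 0.18 in the authors' deposited table. Intercalated cell genes fell in 9 of 20 cases (10 adjusted over the list alone, adjusted p = 2.42e-08), including Slc4a1, the anion exchanger of acid-secreting cells, at -3.42 ± 0.25 in the authors' deposited table. Of 14 principal cell genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.00560). Mcoln3 was at 1.47 ± 0.17 in the authors' deposited table, and the gene that fell was Rhcg, an ammonia channel. That call was lost with an inter-gene correlation of 0.1 (adjusted p = 0.0558) and with fold changes in place of test statistics (adjusted p = 0.0841, the highest of 7 alternatives, from 0.000509).

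Injury, immune, matrix and proliferation genes rose in 3-week males. Tubular injury genes rose in 17 of 24 cases (17 adjusted over the list alone, adjusted p = 6.94e-21). Dcdc2a was at 2.03 ± 0.18 and Lgals3, galectin 3, at 1.80 ± 0.18 in the authors' deposited table. Immune cell genes rose in 20 of 30 cases (23 adjusted over the list alone, adjusted p = 4.00e-15), fibroblast and matrix genes in 9 of 15 (9 adjusted over the list alone, adjusted p = 7.88e-10) and cell cycle genes in 13 of 29 (20 adjusted over the list alone, adjusted p = 2.40e-07). Examples in the authors' deposited table were Cd4 at 1.82 ± 0.26, Timp1, an inhibitor of matrix proteases, at 3.19 ± 0.29 and Top2a, a topoisomerase of dividing cells, at 1.10 ± 0.26. In the amino acid and integrated stress response list 5 of 20 genes rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.00121). Atf3 was at 2.45 ± 0.24 and Shmt2 at -0.56 ± 0.15 in the authors' deposited table, and the call of Shmt2 was lost with total-count scaling. Podocyte genes fell in 8 of 17 cases (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.00152) and endothelial genes in 8 of 19 (10 adjusted over the list alone, adjusted p = 3.82e-05). Col4a4 was at -1.08 ± 0.16 and Emcn at -0.74 ± 0.15 in the authors' deposited table. Of 10 genes for ERR family members and their partners 5 fell and 1, Esrrg, rose (the same numbers adjusted over the list alone, adjusted p = 0.00280). Esrrb was at -1.75 ± 0.18 and Esrra at -0.88 ± 0.18 in the authors' deposited table. Glycolysis genes fell in 6 of 17 cases and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0364). Ldhb was at -0.71 ± 0.16 and Eno2 at 1.97 ± 0.24 in the authors' deposited table, and this call ended under 5 of 7 alternatives (adjusted p from 0.00176 to 0.487). Gluconeogenesis and ammoniagenesis genes (4 of 9 lower and 1 higher, and 5 and 2 adjusted over the list alone, adjusted p = 0.332) and polycystic and nephronophthisis genes (1 of 27 lower, and 0 adjusted over the list alone, adjusted p = 0.332) did not pass the set test. The first pointed upwards after subtraction of the median of genes of like abundance (adjusted p = 0.678). With libraries scaled to their total counts instead of the authors' size factors, which shifts every log2 fold change by 0.18 upwards, 2126 of 2827 calls were higher in the knockout (75.2%, against 50.8%). The estimated correlation between genes needs values per library and was not computed.

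**Figure D1:**
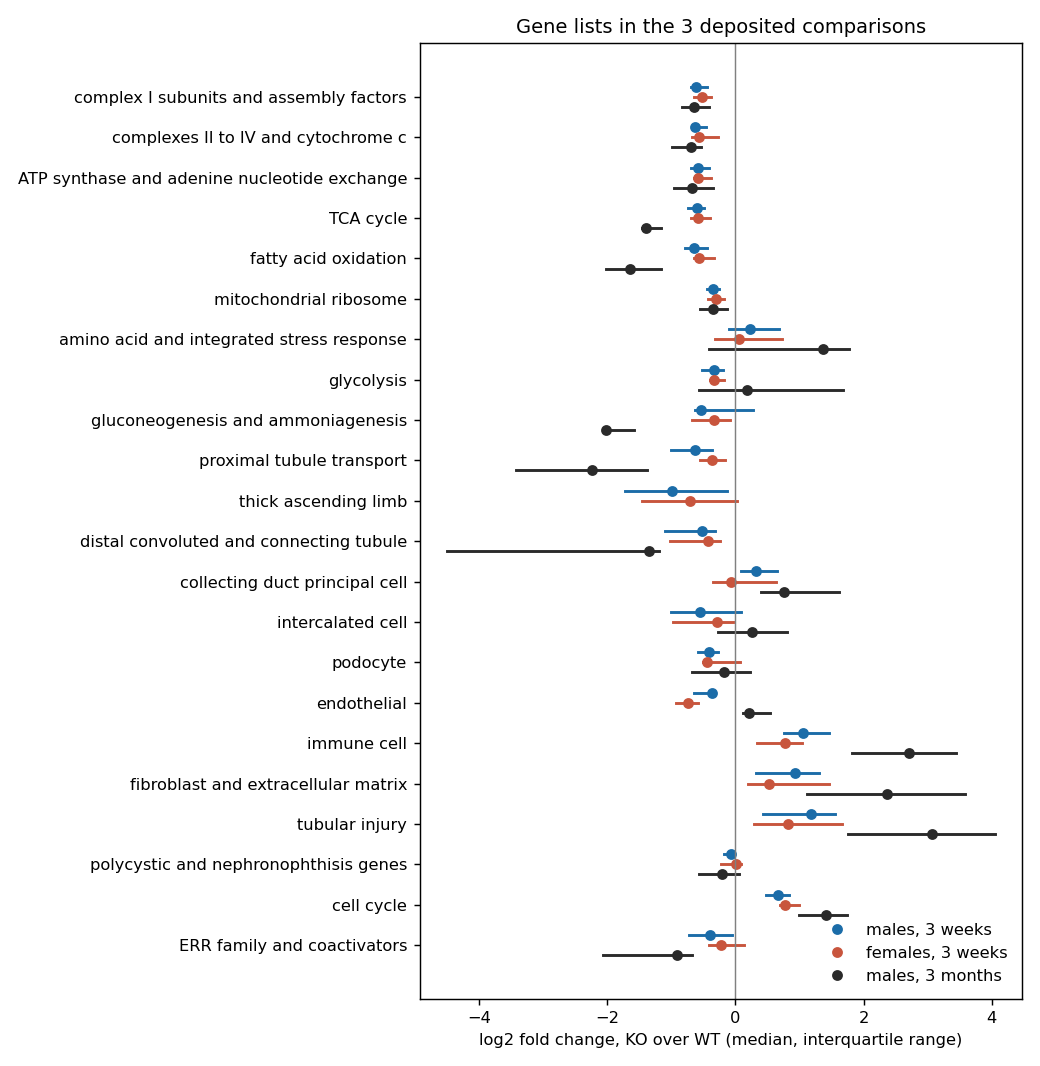
Median log2 fold change (point, horizontal axis, knockout over control) and interquartile range (bar) of the tested genes of each of 22 lists in the comparisons of 3-week males, 3-week females and 3-month males, with no point for a list under 5 tested genes. The 6 mitochondrial lists lie below 0 in all 3 comparisons, and the injury list has medians of 1.17, 0.82 and 3.07.

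In 3-week-old females Gpx6, Tmem207, Atp4a, Klk1, Aqp6 and Pvalb were again among the 8 genes that fell most. Pappa2, Cyp2j13, S100a14, Aldh1l2 and Krt20 were again among the 8 that rose most. In the authors' deposited table the lowest log2 fold changes were -6.57 ± 0.32 for Lrrc66, -6.39 ± 0.23 for Gpx6, -4.87 ± 0.33 for Tmem207, -4.81 ± 0.24 for Atp4a and -4.74 ± 0.16 for Klk1 (SE; adjusted p from 6.09e-46 to 1.95e-200). Aqp6, Pvalb and Gcgr, the glucagon receptor, were at -4.25, -3.46 and -3.43 in the authors' deposited table. The highest values in the authors' deposited table were 5.60 ± 0.22 for Pappa2, 4.65 ± 0.37 for Cyp2j13, 4.36 ± 0.20 for S100a14 and 3.03 ± 0.22 for Aldh1l2 (adjusted p from 4.06e-34 to 3.78e-136). Adamts17, Serpina3g, Krt20 and Serpina10, an inhibitor of coagulation proteases, rose by 2.94, 2.68, 2.61 and 2.60 in the authors' deposited table. Of 14146 tested genes 2651 were called, 1173 higher and 1478 lower. With total-count scaling, which adds 0.15 to every log2 fold change, 2431 of 3288 calls were higher (73.9%, against 44.2%).

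The mitochondrial lists fell in females as well. Of 43 complex I genes 34 fell (35 adjusted over the list alone, adjusted p = 4.74e-22, limma cameraPR). Ndufb9 was at -0.74 ± 0.08 and Ndufa8 at -0.72 ± 0.09 in the authors' deposited table. The list of complexes II to IV fell in 21 of 32 genes (23 adjusted over the list alone, adjusted p = 3.56e-20), ATP synthase in 16 of 21 (17 adjusted over the list alone, adjusted p = 4.16e-15) and the TCA cycle in 17 of 20 (18 adjusted over the list alone, adjusted p = 1.54e-15). Examples in the authors' deposited table were Sdhb at -0.69 ± 0.08, the phosphate carrier Slc25a3 at -0.69 ± 0.08 and Idh2 at -0.97 ± 0.09. Fatty acid oxidation genes fell in 17 of 27 cases (21 adjusted over the list alone, adjusted p = 1.92e-09) and mitochondrial ribosome genes in 34 of 73 (38 adjusted over the list alone, adjusted p = 9.51e-12). Cpt2 was at -0.84 ± 0.14 and Mrps6 at -1.57 ± 0.24 in the authors' deposited table. Glycolysis genes fell in 4 of 16 cases and rose in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0324). Eno2 was again higher, at 1.66 ± 0.22 in the authors' deposited table. Gluconeogenesis and ammoniagenesis genes fell in 3 of 6 cases (3 adjusted over the list alone, adjusted p = 0.0351). These last 2 calls ended under 4 and 6 of 7 alternatives (adjusted p from 0.00416 to 0.233 and from 0.0436 to 0.320).

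Segment genes fell in females along the proximal and distal nephron. Proximal tubule transport genes fell in 14 of 35 cases and rose in 1 (19 and 2 adjusted over the list alone, adjusted p = 7.22e-07). A further 13 genes of this list were outliers without a p-value, 7 positive and 6 negative, with a median of 0.05. With them kept the list still pointed downwards in the set test (adjusted p = 4.39e-06). Slc34a3 was at -2.77 ± 0.23 and Slc9a3, the sodium-proton exchanger, at -1.72 ± 0.24 in the authors' deposited table. The thick ascending limb list (10 of 18 lower, 1 higher, and 10 and 2 adjusted over the list alone, adjusted p = 7.17e-15), the distal convoluted and connecting tubule list (11 of 19 lower, 1 higher, and 14 and 1 adjusted over the list alone, adjusted p = 4.45e-17) and the intercalated cell list (8 of 19 lower, and 10 adjusted over the list alone, adjusted p = 9.04e-10) all passed. Egf at -2.70 ± 0.16, the potassium channel Kcnj10 at -1.12 ± 0.13 and the ammonia transporter Rhbg at -1.59 ± 0.14 were examples in the authors' deposited table. Endothelial genes fell in 15 of 19 cases (17 adjusted over the list alone, adjusted p = 6.10e-12). Robo4 was at -0.81 ± 0.11 in the authors' deposited table. Podocyte genes fell in 6 of 17 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00469, and 0.0693 with an inter-gene correlation of 0.1, the highest of 7 alternatives, from 0.00346). The principal cell list did not pass (2 of 8 higher, 2 lower, and 2 and 2 adjusted over the list alone, adjusted p = 0.682), and the median of its members was -0.07 where the test pointed upwards. With ranks it pointed downwards (adjusted p = 0.850).

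Rising groups in females were those of injury, immune cells, matrix and the cell cycle. Tubular injury genes rose in 16 of 24 cases and fell in 1 (16 and 1 adjusted over the list alone, adjusted p = 2.81e-16). Cd44 was at 2.45 ± 0.25 and Fgg, a fibrinogen chain, at 2.23 ± 0.21 in the authors' deposited table. Immune cell genes rose in 18 of 29 (18 adjusted over the list alone, adjusted p = 5.54e-09), fibroblast and matrix genes in 14 of 25 with 3 lower (16 and 3 adjusted over the list alone, adjusted p = 1.42e-12) and cell cycle genes in 7 of 14 (11 adjusted over the list alone, adjusted p = 0.000247). The authors' deposited table gave 1.21 ± 0.22 for Lyz2, lysozyme of macrophages, 2.01 ± 0.10 for Postn, the matrix protein periostin, and 1.28 ± 0.38 for Bub1, a spindle checkpoint kinase. The amino acid and integrated stress response list (7 of 23 higher, 2 lower, and 7 and 4 adjusted over the list alone, adjusted p = 0.0725), the ERR family list (1 of 10 higher, 3 lower, and 1 and 3 adjusted over the list alone, adjusted p = 0.0624) and the polycystic and nephronophthisis list (1 of 27 higher, 2 lower, and 1 and 1 adjusted over the list alone, adjusted p = 0.682) did not pass. Within them Asns, asparagine synthetase, rose by 1.07 and Esrrb fell by 1.93 in the authors' deposited table.

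In 3-month-old males the genes that rose most included Krt5, Krt14 and the injury marker Lcn2. The authors' deposited table gave log2 fold changes of 10.02 ± 0.50 for Krt5 and 8.37 ± 0.61 for Krt14, keratins of basal epithelial cells, 9.76 ± 0.55 for Gsdmc2 and 8.19 ± 0.60 for Gsdmc3, both gasdermins, and 7.73 ± 0.25 for Lcn2 (SE; adjusted p from 2.87e-40 to 3.45e-206). Fat2, Syt8 and Clca2 rose by 8.00, 7.79 and 7.68 in the authors' deposited table. Gsdmc2 and Gsdmc3 are near-identical relatives and may share reads. Among the genes that fell most, the authors' deposited table gave -6.28 ± 0.54 for Lrrc66, -4.95 ± 0.27 for Slc22a7, an organic anion transporter, -4.64 ± 0.30 for Nepn, -4.60 ± 0.34 for Pvalb, -4.50 ± 0.27 for Klk1 and -4.39 ± 0.18 for Slc34a3 (adjusted p from 1.18e-29 to 4.01e-125). Cyp4b1 and Pde6a were at -4.26 and -4.26 in the authors' deposited table. Of 12828 tested genes 7382 were called, 3819 higher and 3563 lower. With total-count scaling, which adds 0.49 to every log2 fold change, 7105 of 8462 calls were higher (84.0%, against 51.7%).

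Genes of urothelium and of fat cells had positive values at 3 months. The 5 uroplakin genes, which code for the surface plaques of urothelium, had log2 fold changes from 6.47 to 8.39 in the authors' deposited table, which set them aside as outliers with no p-value. Upk1b was at 8.00 ± 0.80 with a mean of 4230 normalized counts in the authors' deposited table. At 3 weeks, Upk1b was at 1.84 ± 0.38 in males and 0.26 ± 0.37 in females in the authors' deposited tables, without a p-value. Of 4 tested blood, fat and adrenal markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone), too few for the set test, and with outliers kept the list rose (adjusted p = 0.000370). Plin1, a lipid droplet protein of fat cells, rose by 4.67 and Car3 by 3.19 at 3 months, and Alas2, an enzyme of red cell precursors, fell by 1.01 in the authors' deposited table. The call of Alas2 was lost with total-count scaling. The blood, fat and adrenal list was fixed before the data were examined, and the uroplakins were chosen once the keratin values had been seen. At 3 weeks no gene of the blood, fat and adrenal list was called, with 1 tested in males and 2 in females.

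Mitochondrial genes were lower at 3 months too. All 27 tested fatty acid oxidation genes fell (27 adjusted over the list alone, adjusted p = 3.95e-19, limma cameraPR), with a median of -1.65. Ppara, the nuclear receptor that drives this pathway, was at -3.01 ± 0.22 and Cpt1a at -2.01 ± 0.09 in the authors' deposited table. All 16 tested TCA cycle genes fell (16 adjusted over the list alone, adjusted p = 5.26e-10). Suclg1 was at -1.69 ± 0.15 in the authors' deposited table. Complex I genes fell in 35 of 42 cases (35 adjusted over the list alone, adjusted p = 1.75e-11). The list of complexes II to IV fell in 28 of 32 genes and rose in 1 (28 and 1 adjusted over the list alone, adjusted p = 1.44e-07), ATP synthase fell in 19 of 23 and rose in 1 (19 and 1 adjusted over the list alone, adjusted p = 3.99e-07), and the mitochondrial ribosome fell in 40 of 73 and rose in 3 (40 and 3 adjusted over the list alone, adjusted p = 0.000149). Uqcrc2 was at -1.33 ± 0.10, the nucleotide carrier Slc25a5 at -1.38 ± 0.11 and Mrps35 at -1.08 ± 0.10 in the authors' deposited table. With total-count scaling the median of the genes of complexes I to IV and ATP synthase together moved from -0.65 to -0.16, and that of the TCA cycle from -1.40 to -0.90. Tested genes with a mean of at least 10000 had a median log2 fold change of -1.05 in this table, and once the median of genes of like abundance was subtracted the call of complexes II to IV was lost (adjusted p = 0.0673, the highest of 7 alternatives, from 1.75e-08). The call of ATP synthase was lost too (adjusted p = 0.547, the highest of 7, from 3.73e-07). The mitochondrial ribosome missed the threshold with an inter-gene correlation of 0.1 (adjusted p = 0.103, the highest of 7, from 2.28e-06). Gluconeogenesis and ammoniagenesis genes fell in 4 of 5 cases (4 adjusted over the list alone, adjusted p = 0.00157). Ldhd was at -3.00 ± 0.35 in the authors' deposited table. Glycolysis genes went both ways (6 of 14 higher, 4 lower, and 6 and 5 adjusted over the list alone, adjusted p = 0.209). Hk2, a hexokinase, was at 4.76 ± 0.44 and Slc16a3, a lactate exporter, at 4.17 ± 0.33 in the authors' deposited table.

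Most genes of the segment lists at 3 months lacked a p-value because the authors set them aside as outliers. This held for 37 of 49 proximal tubule transport genes, all with negative fold changes and a median of -2.08. Of the 12 that were tested, 11 fell (11 adjusted over the list alone, adjusted p = 1.46e-14). Slc7a9, a cystine transporter subunit, was at -2.29 ± 0.09 and Slc6a19, a neutral amino acid transporter, at -3.39 ± 0.22 in the authors' deposited table. Distal convoluted and connecting tubule genes fell in 4 of 5 cases and rose in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.00108). Trpm6, a magnesium channel, was at -1.19 ± 0.24 in the authors' deposited table, and 17 of 19 outliers of that list were negative. The thick ascending limb list had 4 tested genes, below the minimum of 5, of which 1 rose and 1 fell (1 and 1 adjusted over the list alone), and 13 of its 17 outliers were negative, with a median of -0.96 over the 17. With them kept the list pointed downwards and did not pass (adjusted p = 0.143). Cldn10 was at -1.66 ± 0.27 and Slc9a4 at 2.90 ± 0.36 in the authors' deposited table. Principal cell genes rose in 5 of 8 cases (5 adjusted over the list alone, adjusted p = 0.00719), led by the transcription factor Elf5 at 5.21 ± 0.34 and Fxyd4 at 2.58 ± 0.17 in the authors' deposited table. Of the 11 outliers of the principal cell list 8 were positive and 3 negative, with a median of 1.33. The intercalated cell list did not pass (2 of 8 higher, 2 lower, and 2 and 2 adjusted over the list alone, adjusted p = 0.0903), and its 15 outliers were all negative, with a median of -1.23. With them kept the list pointed downwards (adjusted p = 0.350).

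Immune cell genes rose in 26 of 27 cases at 3 months (26 adjusted over the list alone, adjusted p = 4.23e-26). Lyz2 was at 5.77 ± 0.20 and H2-Ab1, a class II histocompatibility gene, at 2.81 ± 0.09 in the authors' deposited table. Tubular injury genes rose in 18 of 21 cases (18 higher and 1 lower adjusted over the list alone, adjusted p = 5.25e-25) and fibroblast and matrix genes in 18 of 20 (19 adjusted over the list alone, adjusted p = 9.78e-13), with the adhesion molecule Vcam1 at 4.05 ± 0.18 and the matrix protease Mmp2 at 3.80 ± 0.17 in the authors' deposited table. In the same comparison the 5 uroplakin genes of urothelium were at 6.47 to 8.39 and Plin1 of fat cells at 4.67 in the authors' deposited table. Cell cycle genes rose in 18 of 22 and fell in 1 (19 and 1 adjusted over the list alone, adjusted p = 0.0114), and amino acid and integrated stress response genes rose in 14 of 20 and fell in 5 (14 and 5 adjusted over the list alone, adjusted p = 0.0114). Mcm3, a replication helicase subunit, was at 1.98 ± 0.19 and Nupr1 at 3.51 ± 0.22 in the authors' deposited table. Of 6 genes of the ERR family and partners 5 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.0138). Ppargc1b, a coactivator of ERR receptors, was at -2.43 ± 0.32 in the authors' deposited table. Those 3 calls were lost with an inter-gene correlation of 0.1 (adjusted p = 0.127 for cell cycle, 0.126 for stress response and 0.0523 for ERR family). With a correlation of 0.05 the cell cycle and stress response calls were lost as well (adjusted p = 0.0538 for each). The cell cycle call was also lost with total-count scaling (adjusted p = 0.112) and after subtraction of the abundance median (adjusted p = 0.220). Over 7 alternatives the adjusted p ranged from 0.000368 to 0.220, from 0.00851 to 0.126 and from 0.00726 to 0.0523, in that order. The podocyte list (2 of 10 higher, 4 lower, and 2 and 4 adjusted over the list alone, adjusted p = 0.363), the endothelial list (3 of 14 higher, 2 lower, and 3 and 2 adjusted over the list alone, adjusted p = 0.608) and the polycystic and nephronophthisis list (7 of 20 lower, and 6 adjusted over the list alone, adjusted p = 0.0903) did not pass. Cd34 was at 1.49 ± 0.21 in the authors' deposited table.

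The sex chromosome genes were read as a check of the labels. The source description of the 3 knockout kidneys of 3 months says female where the other labels say male. Xist, the RNA of the inactive X chromosome, had a mean of 23848 normalized counts in the female table, 17.5 in 3-week males and 11.9 in 3-month males in the authors' deposited tables. Ddx3y, on the Y chromosome, had means of 3323 in 3-week males and 1477 in 3-month males in the authors' deposited tables, and it fell by 0.65 at 3 months, a call lost with total-count scaling. Of the 5 markers, 3 fell at 3 months (3 adjusted over the list alone). None of the 3 tested in 3-week males passed, and no marker was tested in females. The tables were normalized separately, so these levels are set side by side only for their order of magnitude. At that order, the Xist mean of 11.9 argues against a female kidney among the libraries that entered the 3-month comparison. It says nothing of a labelled kidney that did not enter.

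Genes called in all 3 comparisons included those of kallikrein, parvalbumin and a phosphate transporter on the falling side. Of 11928 genes tested in all 3, 970 were called with the same sign in each, 522 higher and 448 lower, where independent lists of these sizes would share 42.6 (21.3 higher and 21.4 lower). With total-count scaling the split was 991 higher and 163 lower, against 155 and 1.95 for independent lists. By the labels the comparisons share no libraries, though which libraries entered each table is not known. Klk1 lies on chromosome 7 from 44225360 to 44229618 on the plus strand and Krt20 on chromosome 11 from 99428403 to 99438150 on the minus strand (GRCm38). The fallers with the largest mean fold change were Klk1, Pvalb, Slc34a3, Gcgr, Dusp15, a phosphatase, and Slc22a7, with log2 fold changes in the authors' deposited tables from -4.95 for Slc22a7 at 3 months to -1.52 for the same gene in females. Among the risers were S100a14 at 4.27 ± 0.22, 4.36 ± 0.20 and 7.35 ± 0.33 and Krt20 at 4.08 ± 0.33, 2.61 ± 0.33 and 5.38 ± 0.47 in the authors' deposited tables, in the order 3-week males, 3-week females and 3-month males. Uroplakin genes of urothelium also had high values at 3 months, and how far urothelial RNA adds to these 3-month values was not tested. Serpina10, Gabrp, a GABA receptor subunit, Serpina3g and Thy1 were the other risers, between 1.91 for Gabrp in females and 6.86 for Gabrp at 3 months in the authors' deposited tables. Serpina3g has near-identical relatives that may share its reads.

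**Figure D2:**
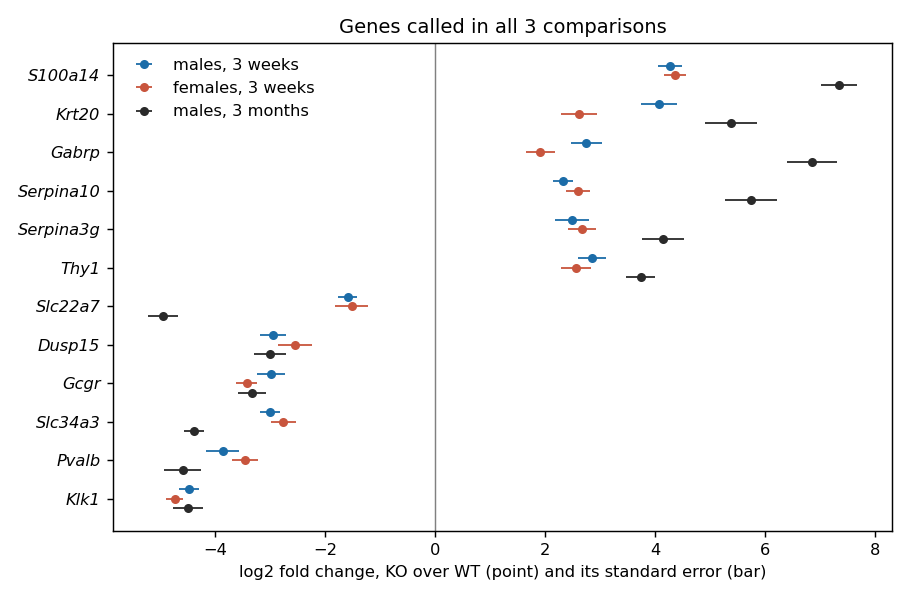
Log2 fold change (point, horizontal axis, knockout over control) and standard error (bar) of the 6 rising and 6 falling genes with the largest mean fold change among those called in the comparisons of 3-week males, 3-week females and 3-month males. S100a14 reaches 7.35 at 3 months, and Klk1 lies between -4.74 and -4.48.

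Males and females of 3 weeks shared 690 rising and 811 falling calls among 13737 genes tested in both, against 92.1 and 117 for independent lists, and no gene was called in opposite directions. Across those genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.86 and a Spearman correlation of 0.77. Males of 3 weeks and 3 months shared 917 rising and 658 falling calls among 12355 genes, against 303 and 243. In this pair 9 genes were higher in the first and lower in the second and 41 the other way, where independent lists would give 289 and 254. With total-count scaling these were 14 and 37, against 181 and 236. The correlations across genes were 0.68 and 0.61 in this pair. Females of 3 weeks and males of 3 months shared 727 and 707 calls among 12207 genes, against 282 and 321, with 31 genes higher in the first and lower in the second and 102 the other way, where independent lists would give 273 and 332. With total-count scaling these were 48 and 114, against 217 and 340, and 63 of the 133 opposite calls of this pair were kept. The interaction of genotype with sex or age, and the differences between control groups, need values per library in 1 fit and were not tested as planned.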

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

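The tests of urothelium and skin RNA were written before the markers' values had been seen. The tests of differences between tables, total-count scaling, abundance, short transcripts, the proximal tubule share, standard errors and depth were chosen after the values they rest on had been seen.

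In males, 50 of 12355 genes tested at both ages were called in opposite directions, 41 lower at 3 weeks and higher at 3 months and 9 the other way. Independent lists would give 254 and 289, so opposite calls were rarer than chance gives. With total-count scaling there were 51, of which 23 were among the 50, and the 3-week calls of Abcc3, Gpr81 and Angpt2 were lost. A difference of 2 fold changes called with opposite signs passes its test by construction, so that test adds nothing for these genes. Abcc3, an export pump for organic anions, went from -0.46 ± 0.17 to 5.40 ± 0.41 in the authors' deposited tables, a difference of 5.85. The difference was 3.58 for Gpr81, the lactate receptor, 3.56 for Angpt2, a vascular growth factor, and 2.70 for Lfng, a modifier of Notch receptors. Cyp7b1, an oxysterol hydroxylase, went from 1.57 ± 0.21 to -3.20 ± 0.34 in the authors' deposited tables, a difference of -4.77, and Sdc2 had a difference of -1.39. Over all 12355 genes the difference between the ages passed for 3418, of which 2400 had the same sign at both ages and so differed in size. The test was not repeated with total-count scaling. Whether the 2 tables were moderated alike is not given in the sources used here, which bears on the size of a difference and not on the signs. Between the sexes at 3 weeks no gene was called in opposite directions, and the same test of the difference passed for 0 of 13737 genes after adjustment and for 237 at an unadjusted p under 0.05. Chance alone would give 687 in a test that keeps its level, so this one was conservative on these values, and the 0 does not show that the sexes responded alike.

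Krt5 and Krt14 were among the largest rises at 3 months. RNA of skin was tested by Krt1, Krt10 and Lor, with a median log2 fold change of 0.91, Krt10 at -0.78, and means of 2.37, 110 and 3.51 normalized counts in the authors' deposited table, far below the 1136 of Krt5, so keratinized skin is not a likely source. A further marker named for this test was not analysed here, and Krt1 and Lor lay near the floor of the table. RNA of urothelium is a candidate source: the median over Upk1a, Upk1b, Upk2, Upk3a and Upk3b was 7.13, where at least 2 was asked for, and Krt5 is itself expressed in basal urothelium. Whether more of the renal pelvis or ureter was dissected with these kidneys, or urothelium grew in them with the genotype or the disease, stays open, and no value per library was at hand to say whether 1 kidney carries it.

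For the fall of oxidative phosphorylation and TCA cycle genes, total-count scaling moved the median of the 4 lists from -0.61 to -0.43 in 3-week males and from -0.56 to -0.41 in females, with the third quartile below 0 in both, so it does not account for the fall at 3 weeks, nor for that of the TCA cycle list at 3 months, which went from -1.40 to -0.90, while the lists of complexes I to IV and ATP synthase together went from -0.65 to -0.16 at that age, with the third quartile at 0.07, and how far scaling may account for their fall cannot be told. The short ribosomal protein genes had medians of 0.13 in 3-week males (75 genes), 0.0513 in females (67 genes) and 1.21 at 3 months (74 genes, outliers kept because 11 were tested), with first quartiles above the third quartile of the lists in each table. This argues against a loss of short transcripts at 3 weeks. At 3 months the rise of these genes was large and rested mostly on outliers. A rise of that size could hide a loss of short transcripts, so the test cannot decide at that age. A lower share of proximal tubule RNA alone would raise the other segments alike. In 3-week males the thick ascending limb median (-0.99) lay below that of principal cells (0.32) by a difference of -1.31 (permutation test, 20 and 14 genes, p = 0.00631). The permutation treats the genes of a list as independent. A lower proximal share beside a separate fall of thick ascending limb genes would give the same values, so this test does not exclude it. Against 10000 random lists matched on abundance, the median of -0.61 in 3-week males lay below the central 95% (-0.19 to -0.03) and so did that of -0.70 in 3-month males (-0.55 to -0.22) and the -0.74 of complex I and TCA cycle genes alone (-0.56 to -0.14), while the -0.68 of complexes II to IV and ATP synthase at 3 months lay inside it (-0.74 to -0.19), so that a general fall of abundant transcripts may account for those 2 lists at that age. This split matches the lists that kept and lost their calls after subtraction of the abundance median, so it is no independent evidence. The genotype, a change within the remaining cells and a loss of several cell types together stay open.

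Far more genes were called in males at 3 months than at 3 weeks, 7382 against 2540. Among 9749 genes with a mean of at least 100 in both, 5505 were called at 3 months and 1278 at 3 weeks. With the standard errors of the 3-week table the 3-month fold changes still gave 5084 calls. The 3-week fold changes gave 1642 calls with the standard errors of 3 months. On these swaps smaller errors account for a part at most. Where values are moderated, fold changes and errors move together, so a swap cannot fully separate them. Greater depth does not account for the larger number of calls, since the mean total at 3 months was 0.396 of that at 3 weeks and the approximate library totals, in units of 1e6, lay between 15.2 and 26.0 against 39.5 to 57.1. The median absolute log2 fold change was 0.45 at 3 months and 0.20 at 3 weeks, with any moderation of the tables left as deposited. Age stays open as an explanation, untested, as do the urothelial and fat RNA described above and the choice of libraries in each table.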

How the results depend on the processing

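All alternatives were chosen after seeing the data. At an adjusted p under 0.01, 1681 genes were called in 3-week males, 1710 in females and 598 in all 3 comparisons (2540, 2651 and 970 at 0.05), and with an absolute log2 fold change of at least 1 there were 1029, 731, 3669 in 3-month males and 280 in all 3 (226 higher and 54 lower), because each is a stricter threshold. All other counts of genes stayed within 1.5 times (2188 to 2827 in 3-week males, 2311 to 3288 in females, 5748 to 8478 in 3-month males and 731 to 1302 in all 3), as did the counts of called lists (18 to 20, 15 to 18 and 12 to 17, from 20, 18 and 16). 3 lists that were not called turned direction: gluconeogenesis in 3-week males after subtraction of the abundance median (adjusted p = 0.678), principal cell in females with ranks (0.850) and intercalated cell at 3 months with outliers kept (0.350). The intercalated cell list turned because its 15 outliers, all negative with a median of -1.23, joined 8 tested genes with a median of 0.26. For the other lists the cause was not tested. Total-count scaling turned the log2 fold changes of Lor (to 0.0686) in 3-week males and of Nepn (to 0.00953) in females, neither of them called, and the cause is the shift itself. It also ended the calls of 7, 4 and 5 named genes in 3-week males, females and 3-month males and added 1, 0 and 3, while an adjusted p under 0.01 ended those of 10, 3 and 3, an absolute log2 fold change of at least 1 ended those of 33, 27 and 7, and low genes kept ended that of 1 in 3-week males. Over all genes, total-count scaling kept 1992 of 2540 calls in 3-week males, 2030 of 2651 in females and 5176 of 7382 in 3-month males. Calls lower in the knockout at 3 months went from 3563 to 1357. Named genes were mostly picked for large fold changes or small p-values, so their tally understates this. Of the lists not called, stress response in females passed with fold changes (adjusted p = 0.0242) and glycolysis at 3 months after subtraction of the abundance median (0.0105). The planned count models, normalizations, filters, estimated correlation, fry, pseudocounts, leaving out replicates and other splits of the libraries were not run, since they need values per library. No paired analysis was possible without values per library, and the replicate numbers do not show which kidneys shared a litter. Depth per library is known only approximately, and which library each total belongs to is not, so no limit per library is given.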

Other observations

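Fat cell genes and the urothelial genes both had positive fold changes at 3 months. Whether they were high in the same kidneys cannot be told without values per library. Cfd, the adipose serine protease adipsin, had a log2 fold change of 5.57 ± 0.66 and a mean of 5499 normalized counts, Cidec one of 4.96 ± 0.58 and Adipoq, adiponectin, one of 4.68 ± 0.68 in the authors' deposited table, all without a p-value. At 3 weeks the same 3 genes lay between -0.09 and 0.11 in the authors' deposited tables.

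Some genes with large rises at 3 weeks had negative values at 3 months that carried no p-value. Cyp2j13 was at 4.25 ± 0.31 in 3-week males and -2.24 ± 0.64 in 3-month males, and Cyp24a1 at 2.69 ± 0.28 and -3.05 ± 0.44, in the authors' deposited tables. These genes were singled out after their values were seen, and the difference was not tested.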
